A study of Homo sapiens with 16 samples.

How the data were processed

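The series holds 16 samples of H1 human embryonic stem cells, an established pluripotent line. 7 are RNA-seq libraries of polyadenylated RNA and 9 are chromatin samples (6 with antibodies to the histone marks H3K27me3 or H3K4me3 and 3 inputs). The RNA libraries are 1 untreated control and 6 treated cultures, given Activin A (25 ng/ml), Wnt3a (25 ng/ml) or both for 6 h or 24 h. Groups were taken from the sample labels. The chromatin samples are not analysed here, so nothing below measures a histone mark. Per the labels' protocols, cells grew on matrigel in a medium with N2 and B27 supplements and were treated in a medium with B27. The labels give the control no treatment and state no culture carried through the medium alone, nor the time at which the control was collected.

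Per the submitters' processing notes, the tools were STAR 2.4.0d, Cufflinks 2.2.1, Cuffnorm, Bowtie 1.1.0 and MACS2 2.1.0 with the hg19 genome; the role of each, the options and the annotation release are not given in the sources used here. The authors deposited 1 table of FPKM values (fragments scaled by transcript length and by the number of mapped fragments) for 34813 genes with 1 column per RNA library, in the layout of a Cuffnorm gene table. A second deposited table pairs each gene identifier with a symbol and a genomic span. FPKM values are estimates divided by gene length and library size, not counts, so no count test was used. Coordinates are those of the files (hg19), written with the first base as 1. Spans of overlapping genes were merged in the files, so that a span can be wider than its gene; 4244 of the genes analysed share a span with another analysed gene. Whether counting used strand is not given in the sources used here, and values of overlapping or antisense genes and of near-identical gene copies, such as the histone genes, are uncertain.

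The columns summed to between 657024 and 712279 FPKM. The number of fragments behind them is unknown, but relative depth could be read from the low values, which fall in steps. For genes under 0.3 FPKM in both libraries, the most common ratio to the control gave relative depths of 1.51 (Activin, 6 h), 1.09 (Wnt3a, 6 h), 1.08 (both, 6 h), 1.33 (Activin, 24 h), 1.32 (Wnt3a, 24 h) and 1.14 (both, 24 h), with the control at 1. After this adjustment, 1217 of 5339 low genes (22.8%) had values (all under 0.5 FPKM) that were whole multiples of their smallest value within 3%, and that smallest value had a median of 0.0270 FPKM (quartiles 0.0163 and 0.0599). Values near 1 FPKM therefore rest on few fragments in short genes and on more in long ones.

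Genes at 1 FPKM or more in at least 1 of the 7 libraries were kept. The plan also left out transcripts under 300 nt, but the length column of the deposited table is empty. Genes with small-RNA symbols or a genomic span under 300 nt were left out in its place (231 genes, of which 21 reached 1 FPKM), and 14068 genes remained. A change is the difference in log2(FPKM + 1), which understates the change of genes with low values. With 1 library per condition there is no replicate error, no test and no p-value. A fixed size rule was used: a gene was counted as higher or lower when its difference reached 1 log2 unit. An exact 0 can be a failed estimate or a gene without expression, and the values do not tell these apart. At 0 in all 7 libraries are 1574 protein-coding genes. No fold is given against a library in which a gene is listed at 0. Differences between effects that involve such a library are given in FPKM.

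The comparisons were each treatment against the control (6), 24 h against 6 h of each treatment (3), the combined treatment against the highest and lowest of the control and both single treatments at each time, and 4 correlations across genes between the effect of one factor alone and its effect in the presence of the other. The last used pairs of differences that share no library. All 6 comparisons with the control share that 1 library, so no overlap between them is reported. 26 gene lists were fixed: pluripotency, primitive streak and mesendoderm, definitive endoderm, early mesoderm, Activin/Nodal targets, Wnt/beta-catenin targets, neuroectoderm, BMP-SMAD1/5 targets, PRC2 and H3K27 demethylases, H3K4 methylation complexes, Activin/Nodal pathway components, Wnt pathway components, FGF/ERK feedback, Notch targets, epithelial-mesenchymal transition, immediate early genes, heat shock and unfolded protein response, p53 targets, sterol synthesis, hypoxia and glycolysis, cell cycle, HOX genes, trophoblast and amnion markers, fibroblast markers, primordial germ cell markers and housekeeping genes. For each list with at least 3 members kept, the median change was ranked among 10000 random lists of the same size drawn from the same 20 bins of mean expression. The percentile describes these libraries only.

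Named genes were chosen by rule: for each of the first 9 comparisons the 8 largest rises and 5 largest falls among genes at 5 FPKM or more in the higher library, the same numbers for the combined against the single treatments, up to 4 members per list that passed the size rule (or the 2 with the highest control value), and 20 genes of the pathways named in the design, in every case. The lists, comparisons, size rule and named-gene rule were fixed before the data were examined, as were 5 alternatives: a pseudocount of 0.1, a minimum of 5 FPKM, no minimum, libraries rescaled to a median ratio of 0 to the control on the log2 scale, and short RNAs kept. An alternative with protein-coding genes only (12592 genes, RefSeq biotype by symbol; 33109 of the 34813 identifiers matched the name table) was added after seeing the data, as were 2 that leave out the replication-dependent histone genes, from all genes and from the protein-coding ones. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. The size rule was tested on simulated data for the combined treatment at 24 h with 14068 genes: it found 49 of 50 genes raised by 1.5 log2 units, 44 of 50 lowered by 1.5, 50 of 50 raised by 3 and 50 of 50 lowered by 3, and 1 unchanged gene passed. The simulation assumed the same fragments per FPKM and the same small spread for every gene. It held no failed estimates, and the changed genes averaged 5 FPKM or more. It therefore checks the calculation and does not show how often scatter of the real libraries passes the rule.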

Results

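RNA of H1 human embryonic stem cells was measured after Activin A, a ligand that signals through SMAD2 and SMAD3, after Wnt3a, which stabilises beta-catenin, and after both, at 6 h and 24 h. The question named by the study is how Activin signalling starts mesendoderm differentiation, the step at which pluripotent cells take on the fate shared by mesoderm and endoderm. Each of the 7 conditions had 1 library, so no value below has a replicate error and no difference could be set against a spread between replicates. Between 13128 and 13261 genes per library reached 1 FPKM. Relative depth ranged from 1 in the control to 1.51 in the library given Activin for 6 h. Across 14068 genes, log2(FPKM + 1) in the treated libraries correlated with the control at r = 0.988 to 0.992 (genes are not independent replicates). Housekeeping genes did not pass the size rule of 1 log2 unit in any comparison with the control (0 of 15), and ACTB was at 5666 FPKM in the control and between 5351 and 6205 FPKM in the treated libraries.

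After 6 h of Activin alone the secreted Nodal antagonists and NODAL were higher than in the control. CER1 (ENSG00000147869.4, chromosome 9, 14719722 to 14722715, hg19) was at 10.4 FPKM in the control and 192 FPKM after Activin (log2 change 4.08). LEFTY2 (chromosome 1, 226124111 to 226129189) went from 3.90 to 81.1 FPKM (4.07), LEFTY1 from 15.8 to 152 FPKM (3.19) and NODAL (chromosome 10, 72192071 to 72201423) from 16.1 to 67.7 FPKM (2.01). LEFTY2 and LEFTY1 lie in spans shared with other genes. Of the 14 Activin/Nodal targets measured, 6 passed the size rule upward and 0 downward, and the list's median change of 0.83 exceeded those of all random lists. Of 18 Wnt/beta-catenin targets only SP5 passed (1.34), with a list median of 0.26 at percentile 99.99. Among 11 primitive streak and mesendoderm genes, FGF8 (1.39) and MIXL1 (1.09) passed. The median of that list, 0.21, stood at percentile 99.3 of random lists, but inside the middle 95% with a minimum of 5 FPKM (95.03) and with no minimum (95.99). In total 82 genes were higher and 43 lower. Of the 82, 33 were listed at 0 in the control, and among protein-coding genes, an alternative added after seeing the data, the counts were 33 and 13. Histone genes transcribed in S phase, whose mRNAs lack a poly(A) tail, made up 4 of the 82, and without them, a choice also added after seeing the data, 78 genes were higher, 29 of them protein-coding. Of the falls, BAALC went from 13.7 to 1.80 FPKM (-2.39), HMSD from 8.85 to 1.12 FPKM (-2.22) and the non-coding RP13-20L14.6 from 9.20 to 0.828 FPKM (-2.48). All of these shared spans with other genes. RP11-359D14.3 was at 101 FPKM in the control and listed at 0 in all 6 treated libraries. For HMSD and RP13-20L14.6 too the control lay 1 log2 unit above all 6. BAALC was lower than the control in all 6, by -0.59 with Wnt3a alone at 6 h and -2.04 at 24 h. The differences of these 4 genes from the control therefore cannot be credited to one factor.

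After 6 h of Wnt3a alone feedback inhibitors and transcription factors of the Wnt pathway were higher than in the control. SP5 (chromosome 2, 171571861 to 171574588), a direct beta-catenin target, went from 1.57 to 14.8 FPKM (2.62), NKD1 from 1.03 to 10.8 FPKM (2.54), DKK1 from 1.26 to 5.84 FPKM (1.60), LEF1 from 3.90 to 12.4 FPKM (1.45) and AXIN2 from 8.69 to 22.6 FPKM (1.28). Of the 18 Wnt/beta-catenin targets measured, 7 passed the size rule upward and 0 downward, with a median change of 0.83 above all random lists. NODAL was at 74.3 FPKM (2.14), and between 65.7 and 74.3 FPKM in all 4 libraries given a single factor. For NODAL, SP5 and AL133168.3 the control lay 1 log2 unit below all 6 treated libraries, so their difference from the control cannot be credited to one factor. EOMES, a T-box factor of mesendoderm, went from 0.643 to 4.90 FPKM (1.85). NODAL and EOMES were the 2 of 14 Activin/Nodal targets past the rule, and the median of that list, 0.31, exceeded those of all random lists. FST, which binds and blocks Activin, went from 14.4 to 38.6 FPKM (1.37), and the homeobox gene MSX1 from 1.87 to 10.2 FPKM (1.96). The log2 differences of CER1 and LEFTY2 were 0.67 and 0.23, under the size rule. EOMES alone of 11 primitive streak and mesendoderm genes passed, and the list median of 0.22 stood at percentile 99.46 of random lists, but at 94.4 with no minimum. In total 85 genes were higher and 43 lower, and 49 and 16 among protein-coding genes. Histone genes were 22 of the 85, and without them 63 were higher, 27 of them protein-coding. SMARCA5-AS1 (-2.09), RP11-3P17.5 (-2.31) and HMSD (-3.08) were among the 5 largest falls. For RP11-3P17.5 and HMSD the control lay 1 log2 unit above all 6 treated libraries, so their falls cannot be credited to one factor either.

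Both factors for 6 h gave the highest values of several mesendoderm genes at that time. EOMES (chromosome 3, 27757440 to 27764202) reached 14.3 FPKM (3.22 against the control), MIXL1 8.56 FPKM from 0.353 (2.82), FGF8 16.6 FPKM from 2.11 (2.5) and T, the brachyury gene (ENSG00000164458.5, chromosome 6, 166571144 to 166582188), 2.64 FPKM from 0.109 (1.72). NODAL reached 152 FPKM (3.16), SP5 31.1 FPKM (3.64) and NKD1 19.2 FPKM (3.31). Set against Activin alone and Wnt3a alone instead of the control, NODAL was higher by 1.16 and 1.03 and SP5 by 2.31 and 1.03. CER1 (144 FPKM), LEFTY2 (53 FPKM) and LEFTY1 (91.1 FPKM) were above the control but below their values with Activin alone, by -0.41, -0.61 and -0.73 log2 units. 5 of 11 primitive streak and mesendoderm genes, 7 of 14 Activin/Nodal targets and 11 of 18 Wnt/beta-catenin targets passed upward, none of these lists had a member that passed downward, and their medians (0.69, 0.88 and 1.28) exceeded those of all random lists. The neuroectoderm list had a median of -0.34, below all random lists with the minimum of 1 FPKM but at percentile 25.9 without it. Its member SIX3, a forebrain factor, went from 5.83 to 2.02 FPKM (-1.18). With both factors at 24 h the list's median was 0.06, inside the middle 95% of random lists (percentile 81.3). With a minimum of 5 FPKM that median was -0.04 (percentile 26.9). In total 131 genes were higher and 49 lower, and 90 and 19 among protein-coding genes. Without histone genes, 18 of the 131, the numbers higher were 113 and 72.

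**Figure D1:**
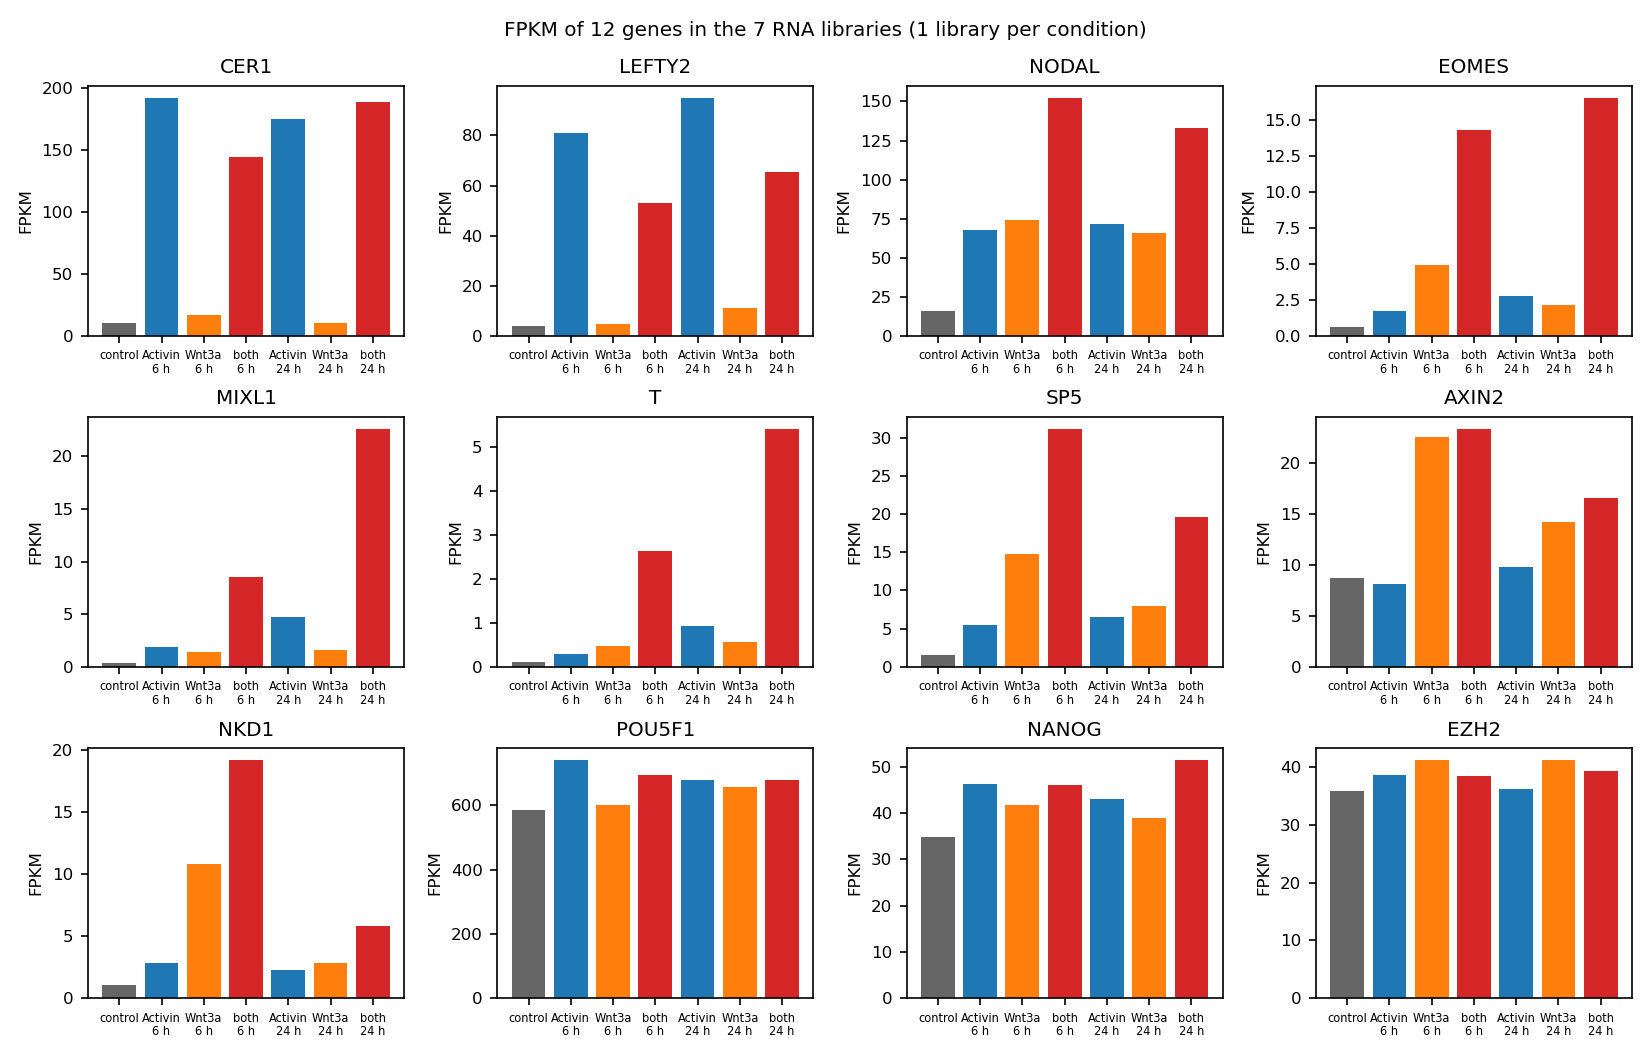
FPKM (vertical axes, linear, from 0) of 12 genes in the 7 RNA libraries (horizontal axes; bars, 1 library each, grey for the control, blue for Activin, orange for Wnt3a and red for both, with 6 h before 24 h). CER1 and LEFTY2 are high in the 4 libraries given Activin, EOMES, MIXL1 and T are highest with both factors, AXIN2 is highest at 6 h with Wnt3a or both, and EZH2 lies between 35.9 and 41.3 FPKM throughout.

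At 24 h of Activin alone the same antagonists stood high. LEFTY2 was at 95 FPKM (4.29), CER1 at 175 FPKM (3.94), LEFTY1 at 157 FPKM (3.23) and NODAL at 71.5 FPKM (2.08). MIXL1 (4.76 FPKM, 2.09), FGF8 (9.47 FPKM, 1.75) and EOMES (2.75 FPKM, 1.19) passed the rule among 11 primitive streak and mesendoderm genes, whose median was 0.74. Of 14 Activin/Nodal targets 7 were higher, with a median of 0.82, and of 18 Wnt/beta-catenin targets SP5 (1.54), DKK1 (1.12) and APCDD1 (1.03) were, with a median of 0.36 above all random lists. In total 75 genes were higher and 39 lower, and 45 and 13 among protein-coding genes, and without histone genes (5) 70 were higher, 40 of them protein-coding. CH25H, which encodes cholesterol 25-hydroxylase, went from 15.1 to 5.13 FPKM (-1.39). MDC1 was at 17.9 FPKM in this library and between 3.22 and 3.85 FPKM in the other 6, in a span shared with another gene.

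At 24 h of Wnt3a alone fewer Wnt targets were past the size rule than at 6 h. SP5 alone of 18 passed (7.97 FPKM, 1.80). AXIN2 was at 14.2 FPKM (0.65), LEF1 at 5.56 FPKM (0.42) and NKD1 at 2.83 FPKM (0.92). Whether the 6 h and 24 h effects differ was not tested. The list's median, 0.41, was above all random lists. CER1, at 10.4 FPKM, was at its control value (-0.01), while NODAL was at 65.7 FPKM (1.96), LEFTY1 at 43.2 FPKM (1.39) and LEFTY2 at 11.1 FPKM (1.30). The latter 3 were the Activin/Nodal targets past the rule, and the list median, 0.22, exceeded those of all random lists. The medians of the Activin/Nodal and Wnt/beta-catenin targets thus lay above the middle 95% of random lists in all 6 comparisons, which share the control. Of 11 primitive streak and mesendoderm genes only FGF8 passed (5.67 FPKM), with a list median of 0.39 above all random lists. GDF3, a relative of Nodal expressed in pluripotent cells, went from 11.5 to 29.2 FPKM (1.27). 4 histone genes transcribed in S phase were among the 8 largest rises: HIST1H3B (7.57 FPKM, 2.47), HIST1H3F (7.24 FPKM, 2.4), HIST1H4L (5.81 FPKM, 2.28) and HIST1H4F (11 FPKM, 2.25). Near-identical copies of these genes make single values uncertain. In total 87 genes were higher and 34 lower, and 44 and 9 among protein-coding genes. Histone genes were 29 of the 87, and without them 58 were higher, 15 of them protein-coding.

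Both factors for 24 h gave the largest number of genes past the rule, 145 higher and 59 lower (90 and 28 among protein-coding genes). Without histone genes (12) 133 were higher, 78 of them protein-coding. MIXL1 reached 22.6 FPKM (4.13), EOMES 16.5 FPKM (3.41), T 5.40 FPKM (2.53), FGF17 5.72 FPKM (2.42), FGF8 15.7 FPKM (2.43) and GSC, a homeobox gene of the organizer, 5.5 FPKM from 0.584 (2.04). 7 of the 11 primitive streak and mesendoderm genes passed upward with a list median of 2.04, and 7 of 14 Activin/Nodal targets with a median of 1.5. Of 18 Wnt/beta-catenin targets 7 passed, with a median of 0.75. In the definitive endoderm list CER1 (188 FPKM, 4.05) passed and the median of 9 genes was 0.67. SOX17, a marker of definitive endoderm, was at 1.22 FPKM against 0.278 in the control (0.80). GDF3 reached 63.8 FPKM (2.38) and the neuropeptide gene GAL 754 FPKM from 221 (1.77). All 4 of these lists had medians above all random lists. In this library the median of 11 fibroblast markers was 0.36, above all random lists, with 0 of them past the rule. Among the falls CH25H went to 3.0 FPKM (-2.01).

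**Figure D2:**
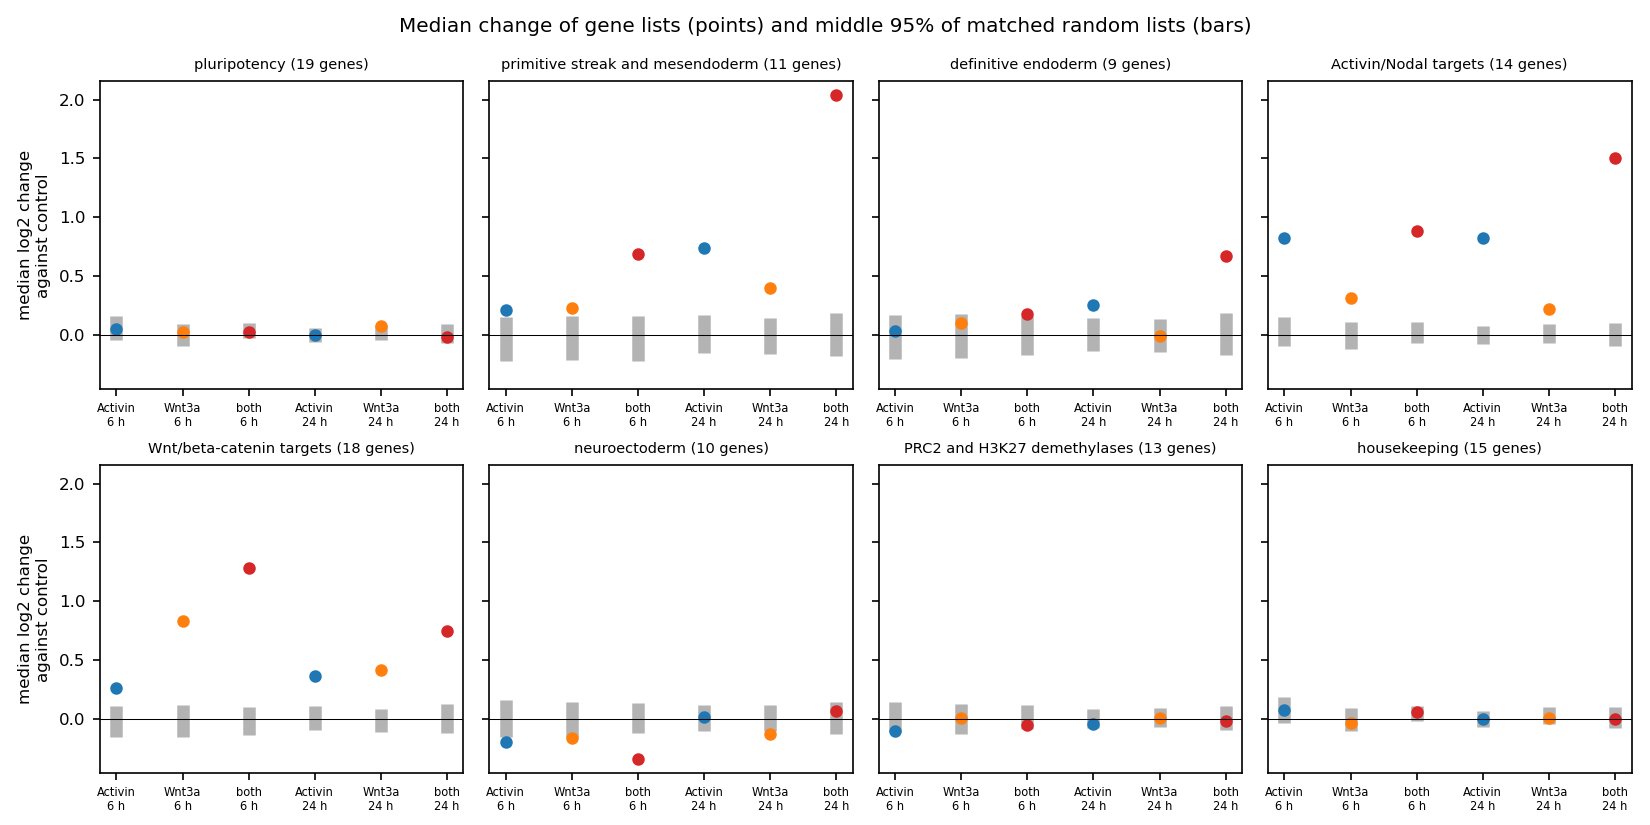
Median log2 change against the control (vertical axis; points, blue for Activin, orange for Wnt3a and red for both) of 8 gene lists in the 6 comparisons (horizontal axis), with the middle 95% of 10000 matched random lists as grey bars. The primitive streak and mesendoderm list reaches 2.04 with both factors at 24 h, while the pluripotency, PRC2 and housekeeping lists lie near 0.

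Few regulators of pluripotency and none of H3K27 methylation passed the size rule. POU5F1 was at 587 FPKM in the control and between 601 and 742 FPKM after treatment, NANOG at 34.9 and between 38.9 and 51.6 FPKM, and SOX2 at 66.4 and between 52.8 and 75.8 FPKM. Of 19 pluripotency genes 0 passed the rule at 6 h, and at 24 h only GDF3 did, with Wnt3a and with both. The list medians lay between -0.02 and 0.07, inside the middle 95% of random lists. TDGF1, a further member that is also in the list of Activin/Nodal pathway components, was not among the genes kept, so neither list covers it. Single members were lower by less than the rule, chosen here after their values were seen: UTF1 in all 6 comparisons (-0.92 with both at 24 h, 5.33 to 2.35 FPKM), FOXD3 by -0.86 with both at 6 h (5.07 to 2.35 FPKM) and DNMT3B by -0.46 and -0.44 with both at 6 h and 24 h. Of the 13 genes of PRC2, the complex that methylates H3K27, and of the H3K27 demethylases, 0 passed in any comparison with the control, with medians between -0.11 and 0.00. The log2 differences ranged from 0.02 to 0.20 for EZH2, its catalytic subunit, from -0.32 to 0.11 for EED and from -0.14 to 0.39 for SUZ12. Those of the demethylase genes KDM6A and KDM6B ranged from -0.11 to 0.20 and from 0.00 to 0.27. The list of H3K4 methylation complexes also holds the H3K4 demethylase genes KDM5A, KDM5B and KDM5C. Its 13 measured members gave 0 genes past the rule (medians -0.02 to 0.09), and its member DPY30 was not among the genes kept. These are mRNA levels and say nothing of enzyme activity.

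The time comparisons set 24 h against 6 h within each treatment. With both factors, GAL (2.02), GSC (1.95), CDA (1.95, from 3.25 to 15.4 FPKM) and GDF3 (1.93) were higher at 24 h, and 82 genes were higher and 48 lower in total. The hormone gene SCT was lower (-1.97, from 5.97 to 0.778 FPKM). With Wnt3a, 53 genes were higher and 37 lower; GDF3 (1.39) was higher, and NKD1 (-1.62), DKK1 (-1.30) and LEF1 (-1.03) were lower. With Activin, 51 were higher and 56 lower, with GPC6 (1.48, from 3.67 to 12 FPKM) and DLL3, a Notch ligand (1.20), among the higher. Against the control, DLL3 was lower at 6 h of Activin (-1.10) and did not pass the rule at 24 h. Protein-coding genes made up 28 and 16, 13 and 11, and 14 and 16 of these counts.

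The combined treatment was next set against the highest and the lowest of the control and both single treatments. At 6 h 19 genes exceeded the highest by 1 log2 unit and 2 lay as far below the lowest; among the former were MIXL1 (1.73), EOMES (1.37), FGF8 (1.11), SCT (1.1), SP5 (1.03) and NODAL (1.03). At 24 h the counts were 38 and 2, with EOMES (2.22), DKK4 (2.13, from 0.702 FPKM with Activin alone to 6.47 FPKM), MIXL1 (2.04), T (1.72) and FGF17 (1.61). Protein-coding genes made up 10 and 0 at 6 h and 15 and 0 at 24 h. With a pseudocount of 0.1 the counts over all genes were 42 and 40 at 6 h and 68 and 34 at 24 h, so the balance of higher to lower depends on the pseudocount. RAPGEF6 had the largest excess at 6 h (2.12, 19.4 FPKM) and was back at 4.28 FPKM at 24 h, in a span shared with other genes. Other libraries also stood 1 log2 unit above their 3 counterparts, in up to 23 genes at 6 h and 27 at 24 h, and in up to 4 and 8 among protein-coding genes.

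The effect of each factor with and without the other was compared across 14068 genes through differences that share no library. Activin effects correlated at r = 0.226 at 6 h and 0.312 at 24 h (Spearman 0.237 and 0.306), and Wnt3a effects at r = 0.216 and 0.207 (0.233 and 0.232). Genes are not independent replicates, so no p is given. Among protein-coding genes r was 0.317 and 0.452 for Activin and 0.331 and 0.318 for Wnt3a. CER1, LEFTY1, LEFTY2, NODAL, MIXL1, FGF8 and SP5 passed the rule upward in both Activin differences at both times. In total 18 genes did so at 6 h and 26 at 24 h, where independent lists would share 0.356 and 0.506 genes. For Wnt3a these were 26 genes at 6 h, among them AXIN2, LEF1, NKD1, SP5, MSX1, FST, EOMES and 6 histone genes (HIST1H1D, HIST1H2AH, HIST1H3B, HIST1H3E, HIST1H4D and HIST2H3D), and 8 at 24 h, against 0.405 and 0.414. Genes lower in both numbered 5 at 6 h and 2 at 24 h for Activin and 3 and 4 for Wnt3a, against 0.122, 0.150, 0.159 and 0.0918. Genes that passed in opposite directions numbered 7 and 4 for Activin and 10 and 8 for Wnt3a. Independent lists would give 0.420, 0.551, 0.519 and 0.397 such genes. Opposite changes thus also exceeded the numbers for independent lists, and for Wnt3a at 24 h they were as many as the genes higher in both. Those numbers are therefore no chance rate, and the excess over them does not count shared effects. The counts of shared and opposite genes were added after seeing the data.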

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

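All tests named here were chosen after the values were seen, except the count of genes in which 1 library stands above the other 6. The results below are named genes whose effects passed the size rule in opposite directions at the 2 times of 1 treatment, or without and with the other factor. None of these differences was tested, since each rests on single libraries.

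The effect of Activin with Wnt3a minus its effect alone was 2.42 log2 units for RP11-386M24.8 at 6 h. The effect of Wnt3a with Activin minus its effect alone was 3.12 log2 units at 6 h and -2.11 at 24 h for SMARCA5-AS1, and -2.60 at 24 h for RPP14. For genes listed at 0 in a library involved, the difference is given in FPKM. It was -16.9 FPKM at 6 h for the clone-named ENSG00000266341.1, and -7.83 FPKM for RP11-212D19.4 and -10.43 FPKM for RP11-386I14.4 at 24 h, the same quantity for either factor. For Wnt3a at 6 h it was -55.97 FPKM for RP11-330A16.1 and 18.12 FPKM for CTC-246B18.10. Between 24 h and 6 h of Wnt3a, the effect on SMARCA5-AS1 differed by 3.17 log2 units and that on RPP14 by 2.43. 1 of these 8 genes, RPP14, is protein-coding by its symbol, 7 share their span with another gene, and 6 are listed at 0 in at least 1 library.

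A group of genes was lower in all 6 treated libraries than in the control, among them HMSD, RP13-20L14.6 and RP11-359D14.3. The control stood 1 log2 unit above all 6 others in 9 genes. Values of the control library alone could account for this: other libraries stood as far above the remaining 6 in 6 to 25 genes, the 25 being in the library given both factors for 24 h, and in up to 12 genes in the rest. The control also stood 1 log2 unit below all 6 others in 3 genes, NODAL, SP5 and AL133168.3, where other libraries did so in 0 to 2 genes. For the part of these rises that all treated libraries have in common, low values of the control alone cannot be told apart from an effect of the treatments. An effect of the change of medium or of both factors alike was not tested for the falls or the rises, and the design has no culture to test it.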

How the results depend on the processing

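The alternatives with protein-coding genes only, without histone genes, and with both restrictions were chosen after seeing the data. 1 result reversed its direction: the median of the definitive endoderm list with both factors at 6 h, 0.18 and outside the middle 95% of random lists, was -0.01 with a minimum of 5 FPKM (percentile 34.44, 5 genes). With no minimum FPKM, rescaled libraries, short RNAs kept or histone genes left out, every count and correlation stayed within 1.5 times; the first cannot add a gene past the rule, since a gene under 1 FPKM everywhere cannot reach it. Pairs below are genes higher and lower, for Activin, Wnt3a and both.

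With a pseudocount of 0.1 the counts against the control rose to 215 and 137, 206 and 155, and 268 and 202 at 6 h, and to 217 and 126, 193 and 123, and 305 and 180 at 24 h. Those of 24 h against 6 h rose to 147 and 134, 141 and 123, and 214 and 142, and those of the combined against the single treatments to 42 and 40 at 6 h and 68 and 34 at 24 h. Correlations fell to 0.137 and 0.175 for Activin and, at 24 h, 0.115 for Wnt3a. Low values weigh more here by construction.

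With a minimum of 5 FPKM fewer genes enter, and the counts were 44 and 15, 48 and 18, and 82 and 17 at 6 h, and 49 and 11, 42 and 13, and 84 and 23 at 24 h. Between times they were 20 and 27, 19 and 17, and 34 and 21, and for the combined against the single treatments 9 and 0 at 6 h and 19 higher at 24 h.

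With protein-coding genes only the counts were 33 and 13, 49 and 16, and 19 lower with both at 6 h, and 45 and 13, 44 and 9, and 90 and 28 at 24 h. Between times they were 14 and 16, 13 and 11, and 28 and 16, and for the combined treatment 10 and 0, and 15 and 0. Wnt3a correlations rose to 0.331 and 0.318. The cause was not tested. With histone genes also left out the counts were 29 and 13, 27 and 16, and 72 and 19 at 6 h, 40 and 13, 15 and 9, and 78 and 28 at 24 h, 14 and 15, 13 and 11, and 28 and 16 between times, and 10 and 0, and 15 and 0 for the combined treatment. The Activin correlation at 24 h was 0.482.

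Of 150 list medians, 148 kept their place inside or outside the middle 95% of random lists with a pseudocount of 0.1, 150 after rescaling, 149 with short RNAs, 149 with protein-coding genes, 150 without histone genes, 147 with both restrictions, 129 with a minimum of 5 FPKM (9 moved outside, 5 inside and 1 reversed) and 138 with none. The sign of the median differed in 13 cases with a minimum of 5 FPKM and 9 with none, among them neuroectoderm with Activin at 24 h (0.01, but -0.17 with 5 FPKM). Germ cell markers had too few members at 5 FPKM, and HOX genes in every setting but no minimum, where 13 were listed above 0. Of 1161 changes of named genes, 63 came to pass the size rule with a pseudocount of 0.1 and 1 ceased to after rescaling. Depth limits genes near 1 FPKM.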

Other observations

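The tests of histone genes and of scatter, and the genes named outside the lists, were chosen after the values were seen; the list medians were planned. ACTC1, ACTA1, MYL7 and NPPB were among the 26 genes higher with Activin at 24 h, both alone and on top of Wnt3a. The cardiac actin gene ACTC1 was at 52.2 FPKM in the control, 125 FPKM with Activin and 124 FPKM with both, against 40.2 FPKM with Wnt3a. The skeletal actin gene ACTA1 was at 72.7, 162, 152 and 68.1 FPKM in the same order. The atrial myosin light chain gene MYL7 was at 11.4, 26.9, 28.6 and 12.9 FPKM, and the natriuretic peptide gene NPPB at 18.2, 37.5, 41.7 and 19.5 FPKM. CDKN2B, a cell cycle inhibitor induced by TGF-beta signalling, was at 3.29 FPKM in the control, 8.88 FPKM with Activin and 16.0 FPKM with both at 6 h. Genes higher at 6 h with Wnt3a, alone and on top of Activin, included WNT10B (1.67 FPKM in the control, 6.08 FPKM with Wnt3a and 7.04 FPKM with both) and TNFRSF11B (2.36, 7.15 and 6.81 FPKM).

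In the neuroectoderm list (10 genes) the medians with Activin and Wnt3a at 6 h were -0.20 and -0.16, at percentiles 0.88 and 2.11 of random lists but 52.1 and 12.2 with no minimum. With Wnt3a at 24 h the median was -0.13, at percentile 1.15 but 52.5 with no minimum, and with Activin at 24 h it was 0.01, at percentile 56.8, but -0.17 and at 0.55 with a minimum of 5 FPKM. In the definitive endoderm list they were 0.18 with both at 6 h and 0.25 with Activin at 24 h, at percentiles 98.47 and 99.91, but with a minimum of 5 FPKM the former reversed to -0.01 (34.4) and the latter stood at 96.5. Sterol synthesis genes had medians of -0.31, -0.17 and -0.30 at 6 h with Activin, Wnt3a and both, at percentiles 0, 0.01 and 0 of random lists, with 0 of 16 past the size rule, and medians of 0.02, 0.02 and 0.09 (percentile 98.52) at 24 h. Immediate early genes had medians of -0.36 at 6 h and -0.25 at 24 h with Wnt3a alone, below all random lists, with 0 of 13 past the rule. Medians of the epithelial-mesenchymal transition list (15 genes) ran from -0.21 to 0.15 and those of fibroblast markers (11 genes) from -0.19 to 0.36. Both were lowest with Wnt3a at 24 h, below all random lists, and fibroblast markers were highest with both factors at 24 h, above all random lists. The transition list stood at 0.15 with both factors at 6 h and 0.11 with Activin at 24 h (percentiles 99.84 and 99.67). It holds epithelial genes (CDH1, EPCAM, CLDN6 and CLDN7) beside mesenchymal ones such as CDH2 and VIM, so its median gives no direction of the transition. Fibroblast markers stood at -0.12, -0.16 and 0.17 with Activin, Wnt3a and both at 6 h (percentiles 2.4, 0.815 and 99.74), and with Activin at 24 h they passed outside the middle 95% with a minimum of 5 FPKM (99.99) and with none (99.94). Medians for early mesoderm ran from 0.01 to 0.08, inside the middle 95%, but with a minimum of 5 FPKM they stood at percentiles 99.71 with both at 6 h and 98.2, 99.66 and 98.93 with Activin, Wnt3a and both at 24 h. BMP-SMAD1/5 targets ran from -0.15 to 0.20, at percentiles 0.765 with both at 6 h, 99.2 with Activin at 24 h (96.98 with a minimum of 5 FPKM) and 99.94 with Wnt3a at 24 h. Activin/Nodal pathway components ran from -0.06 to 0.15, highest with both at 6 h (percentile 99.28, but 96.46 with no minimum), Wnt pathway components from -0.08 to 0.02 and FGF/ERK feedback from -0.11 to -0.01, lowest with Activin at 24 h (percentile 0.67). Notch targets ran from -0.08 to 0.12. Heat shock and unfolded protein response genes ran from -0.11 to 0.17, at percentiles 99.96 with both at 6 h and 0.12 and 1.64 with Activin and Wnt3a at 24 h. The p53 targets ran from -0.13 with Activin at 6 h (percentile 2.4, but 2.83 with a minimum of 5 FPKM) to 0.13 with both at 24 h (98.76), and hypoxia and glycolysis genes from -0.08 with both at 6 h (0.26) to 0.04. Cell cycle genes ran from 0.00 to 0.12, with the medians for Wnt3a alone at percentiles 99.35 and 99.81. Trophoblast and amnion markers ran from -0.03 to 0.24, at percentiles 97.87 with Wnt3a at 6 h (59 with a minimum of 5 FPKM) and 99.84 with Activin at 24 h, and primordial germ cell markers from 0.00 to 0.25, highest with Activin at 24 h (98.05, but 92.4 with no minimum). Other medians inside the middle 95% also moved outside: with a minimum of 5 FPKM, hypoxia (0.47) and trophoblast genes (99.67) with Activin at 6 h and Wnt pathway components (2.18) with Wnt3a at 6 h, and with no minimum, heat shock genes (98.05) and hypoxia genes (0.63) with Activin at 6 h. With a pseudocount of 0.1, trophoblast genes moved outside with Activin at 6 h (97.6) and inside with Wnt3a at 6 h (95.4). Germ cell markers with both at 6 h moved outside with protein-coding genes only (97.69), also without histone genes (98.15). Of 15 HOX genes 0 reached 1 FPKM. Over all lists, 55 of 150 medians lay outside the middle 95% of random lists, where 7.50 would for lists of unrelated genes. Members of a list can vary together, some lists share genes and all comparisons share the control. The 7.50 is therefore no chance rate for these lists, and the excess over it counts no effects. Ribosomal protein genes (80) had a median of 0.20 log2 units above the control with Activin at 6 h and between -0.03 and 0.08 in the other treated libraries. HMOX1 was at 65.0 FPKM in that library and 33.7 FPKM in the control.

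Histone genes transcribed in S phase, whose mRNAs lack a poly(A) tail, were higher in the libraries given Wnt3a. The median change of 57 such genes against the control was 0.77 at 6 h and 1.01 at 24 h with Wnt3a, 0.66 and 0.60 with both, and 0.22 and 0.23 with Activin. Against Activin at the same time, without the control, Wnt3a alone gave 0.63 and 0.80 and both factors gave 0.33 and 0.31, with 11, 22, 6 and 0 genes higher by the size rule. Of 16 S-phase genes with polyadenylated mRNA, 14 at 6 h and 15 at 24 h were above the control with Wnt3a alone. Their upper quartile was at most 0.15, under 0.5 times the smaller histone median (0.38). Against Activin, 10 at 6 h and 16 at 24 h were higher with Wnt3a alone. Their medians were 0.08 and 0.15, and their upper quartiles 0.17 and 0.22. With both factors the medians against Activin were -0.01 and 0.02. The S-phase genes thus rose less than the histone genes. The factor of 0.5 was set after the values were seen. How far either set follows the share of cells in S phase is unknown here, so a larger share stays open. For carry-over of RNA without a tail, 14 genes with small-RNA symbols had upper quartiles of 2.56 at 6 h and 0.46 at 24 h with Wnt3a alone and of 2.08 and 2.14 with Activin, and medians of -0.13 and -0.09 for Wnt3a against Activin. That set holds miRNA loci and RNAs listed at 0. The 4 RNAs of neither kind, chosen after the values were seen, had medians of 0.88 and 1.45 for Wnt3a against Activin. RMRP was at 16.2 FPKM in the control, 344 and 514 FPKM with Wnt3a and 85.1 and 146 FPKM with Activin. In the same order RPPH1 was at 0.594, 18.5 and 20.5, and 3.11 and 5.27 FPKM. RN7SL1 was at 27.8, 262 and 288, and 329 and 131 FPKM. SCARNA9, lower with Wnt3a than with Activin at both times, was at 18.2, 21.2 and 25.0, and 25.1 and 31.3 FPKM. Carry-over therefore cannot be told apart from an effect of Wnt3a on histone mRNA.

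Genes higher with both factors than with either alone may include scatter of single libraries. The combined library stood 1 log2 unit above the other 3 in 19 genes at 6 h, where the Activin library did in 23, and in 38 at 24 h, where others did in at most 27, with 10 and 15 protein-coding genes against at most 4 and 8, so scatter cannot be told apart from an excess by counts at either time. The primitive streak and mesendoderm list had a median excess over the highest of the other 3 libraries of 0.47 at 6 h and 0.73 at 24 h. Both stood at percentile 100 of random lists. The Wnt/beta-catenin targets, which share T with that list, had 0.19 and 0.26 at the same percentile. This argues against scatter that is independent from gene to gene. Genes of a list can move together in 1 culture, so the percentiles cannot tell a difference of that culture from a joint effect. By the same measure the Activin/Nodal targets lay above the middle 95% at 6 h (percentile 98.36) and inside it at 24 h (71.09), but their medians, -0.02 and -0.06, were not above 0, and 7 and 6 of 14 genes lay above the sum of both single effects. Of the 11 mesendoderm genes, 10 at 6 h and 11 at 24 h lay above that sum on the FPKM scale, 3 and 5 of them by 1 log2 unit. Of 18 Wnt targets, a smaller share, 13 and 11 lay above it, 1 and 2 of them by 1 unit. The share of all genes above that sum is not given here, so these counts have no baseline. A joint action of both factors is a hypothesis, and a difference between single cultures stays open.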
